A study of Mus musculus with 7 samples.

How the data were processed

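RNA was sequenced from 7 mouse DRG cultures with the Lexogen QuantSeq 3′ mRNA kit and RiboCop rRNA depletion, per the labels' protocols. The cultures had been grown with NGF and FRDU and treated on day 6 in vitro with 1 µM 11j (4 samples) or vehicle (3 samples) for 4 h. The submitters' processing notes list FastQC 0.11.5, TopHat2 2.1.1 and Cufflinks 2.2.1 with the mouse build mm10, with no role or order; how reads were counted, and on which strand, is not given in the sources used here.

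The deposited table lists 13453 genes with a value for each library. Per the file headers the 4 treated columns are in TPM, and the vehicle columns carry no unit. The values behave as CPM instead, reads scaled by library size with no division by length: the authors' columns sum to between 970063 and 997303, and in each library between 96.7% and 97.7% of genes lie within 0.02 reads of a whole multiple of the same step, whatever their length, so they are treated here as CPM. The step, between 0.0495 and 0.0911 CPM, is taken as 1 read and gives depths of 10977538 to 20205463 reads. Of the 7 columns, all except that of vehicle replicate 1 hold a lowest value other than 1 step, so reads were not rebuilt and no count model was used. No value is 0. The deposited fold column is the ratio of the authors' group averages within 2.12%, and the deposited log2 column is its logarithm. Recomputing the deposited p-values from the file showed that they follow an unequal-variance test on the untransformed values, with Benjamini-Hochberg adjustment over all genes, except for 21 genes whose symbol had become a date number.

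Each column was matched to its sample through the code in the sample's title. Genes with a CPM of at least 1 in at least 3 of the 7 libraries were tested (13418), on log2(CPM + 1), with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05, no covariate). The main test assumed normalized values before the data were examined, and CPM fits that. Before the data were examined, 28 gene lists were also fixed. The 27 with at least 3 measured members were tested with limma's camera function at a preset correlation of 0.01, adjusted over the lists, and 13 passed, 7 higher and 6 lower. With an estimated correlation 0 of the 27 passed (lowest adjusted p = 0.0722), and 7 had an unadjusted p under 0.05. With fry, a rotation test of whether a list's genes move on balance in the same direction, 16 passed. Counts of members past the threshold use the adjustment over all genes. Adjusted over the list alone they are the same, except for immediate-early genes (8 higher and 12 lower), cytokines (5 and 5), p53 targets (4 and 3) and nuclear oxidative phosphorylation genes (24 and 10).

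Genes were named by a rule fixed beforehand: 19 genes chosen from the design, then the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap and whose mean is at least 5 CPM, with predicted genes and pseudogenes counted but not named, and up to 4 members with the smallest p from each list. Other genes named in the text (Srsf1, Srsf5, Rbm3, Son, Snhg14 and Snhg11) were chosen after their values were seen, as list members that fell. The mitochondrial rRNAs were among the largest rises.

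Gene positions and types come from GENCODE M21, on the same build as mm10, which holds 13425 of the 13453 gene identifiers. Near-identical copies were sought by aligning the last 300 bases of each gene's longest transcript to all transcripts with BLAST+ 2.17.0, on the same strand, and a hit of at least 100 bases at 95% identity outside the gene's own position counted as a copy. Overlaps of named genes were read from exons of other genes within their last 1000 bases and from annotated pseudogenes within their span.

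Pearson correlations of log2 values lay between 0.968 and 0.995 within groups and between 0.911 and 0.930 across them. On the reads implied by the step, every pair of libraries differed by more than sampling noise (mean chi-square per gene of at least 8.17), so no library was counted as a duplicate. The first principal component held 78.7% of the variance and separated the groups, and the second (13.0%) set vehicle replicate 1 apart. The test was tried on simulated data for the same comparison with 13163 genes tested. Simulated genes varied independently, with a dispersion of 0.01, and no library stood apart. The test recovered 83.6% of 67 genes changed 1.5-fold, 100% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 8 unchanged genes called. In simulated data without any change it called 0 genes and 0 lists. Some real genes spread more widely, such as Il6 with vehicle (31.0 ± 31.5 CPM), so these rates need not hold for the real libraries. Alternatives left out each library, kept Swiss Webster cultures alone, added strain or the replicate number to the model, and changed the pseudocount, filter, scaling, variance model, weights, threshold and gene-set test. Scripts also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.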

Results

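RNA was measured in 7 cultures of mouse dorsal root ganglion (DRG), the ganglia that hold the cell bodies of sensory neurons together with satellite glia and Schwann cells. On day 6 in vitro, 4 cultures received 1 µM of compound 11j, a selective inhibitor of the kinase SMG1, for 4 h, and 3 received vehicle. SMG1 phosphorylates UPF1, a step of nonsense-mediated decay (NMD), the pathway that degrades transcripts with a premature or otherwise exposed stop codon. All 4 11j cultures and vehicle replicates 2 and 3 came from Swiss Webster mice, and vehicle replicate 1 came from C57BL/6J. Libraries were made with a 3′ mRNA sequencing kit after depletion of ribosomal RNA, so that a gene's reads come mostly from its 3′ end. The step between low values put the depth at 12808239, 20205463 and 12132419 reads in vehicle replicates 1 to 3, and at 14591910, 10977538, 17159038 and 13086494 reads in 11j replicates 1 to 4. At these depths 3 reads correspond to between 0.148 and 0.273 CPM (reads scaled to a common library total, with no division by gene length). Below, levels are CPM as mean ± SD over 3 vehicle and 4 11j libraries, and log2 changes are 11j minus vehicle on the log2(CPM + 1) scale with their standard error (SE), which understates the change of low genes. The labels do not say that the cultures of a group came from separate animals or preparations. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation compare a list with other genes, so they rest largely on the spread between genes. Fisher's exact and permutation tests in the closing section also treat genes as units.

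The comparison of 11j with vehicle asks which transcripts change when SMG1 is inhibited in sensory ganglion cultures, and the series names NMD, the integrated stress response and nociception as its subjects. In a test with a preset correlation, the lists of NMD factors, known NMD targets, snoRNA host genes, splicing factors and stress response genes stood higher with 11j than other genes, whereas those of neuronal, nociceptor and satellite glia markers and of cholesterol synthesis stood lower. Each list also held members that did not pass, and no list passed with an estimated correlation (lowest adjusted p = 0.0722). The list of NMD factors also did not pass among Swiss Webster cultures alone (adjusted p = 0.0590). Of 13418 genes tested with limma, 7623 (56.8%) passed an adjusted p of 0.05, with 3587 higher and 4036 lower in 11j cultures. Changes of at least 2-fold were fewer, with 1160 genes higher and 1053 lower, and 257 genes changed at least 4-fold. In 7732 genes the 4 11j values all lay on the same side of the 3 vehicle values, which chance gives for 5.71% of genes. Among Swiss Webster cultures alone, 8774 genes passed, 4238 higher and 4536 lower. The library codes of the 2 groups follow different series, so a difference in library preparation or sequencing between the groups cannot be told apart from the treatment. In the authors' deposited table, 4072 genes have an adjusted p under 0.05, with 2480 higher and 1592 lower. Those p-values follow an unequal-variance test on untransformed values, so the counts are not directly comparable with those of limma. The same kind of test run here gave 2485 genes higher and 1596 lower.

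Most factors of the NMD pathway had higher transcript levels in 11j cultures. Of 18 measured factors, 10 rose, 2 fell and 6 did not pass. Smg1 itself (chromosome 7, 118131308 to 118243670, mm10) rose from 23.2 ± 0.889 to 39.8 ± 4.18 CPM, a log2 change of 0.75 (SE 0.11). Smg5, which recruits decay enzymes to phosphorylated UPF1, rose by 1.10 (SE 0.11) and Smg9, a subunit of the SMG1 complex, by 1.22 (SE 0.12). Upf2 rose by 0.52 (SE 0.10), Upf1 by 0.67 (SE 0.18) with overlapping groups and with exons of other genes on the opposite strand at its 3′ end, and Upf3a by 1.18 (SE 0.12). Its paralog Upf3b, whose 3′ end has a near-identical copy elsewhere and is therefore uncertain, stood at 35.9 ± 7.76 and 34.2 ± 3.17 CPM and did not pass. Magoh, a core component of the exon junction complex, fell from 294.4 ± 3.74 to 148.1 ± 16 CPM. As a set the factors stood above other genes (camera adjusted p = 0.0323, median log2 change 0.56), but not with an estimated correlation (adjusted p = 0.194) and not among Swiss Webster cultures alone, that is without vehicle replicate 1 (adjusted p = 0.0590). The call was also lost with sample quality weights and with a minimum of 5 CPM (adjusted p = 0.0565 and 0.0776). Its loss with strain as a term (adjusted p = 0.0580) is not a separate check, since that term rests on vehicle replicate 1 alone.

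Transcripts described before as NMD targets included the genes with the largest changes among stress regulators. Gadd45b, a growth arrest and stress gene (chromosome 10, 80930073 to 80932204), rose from 34.8 ± 9.90 to 309.6 ± 16.2 CPM, 8.89-fold (log2 change 3.15, SE 0.16, limma adjusted p = 1.95e-07). Ddit3, which encodes the stress transcription factor CHOP (chromosome 10, 127290774 to 127296288), rose from 46.4 ± 11.9 to 440.4 ± 22.7 CPM, 9.49-fold. Its last kilobase overlaps exons of Mars on the opposite strand, and the strand used in counting is not given in the sources used here. Atf4, the central transcription factor of the integrated stress response, rose 3.37-fold to 1116 ± 39.9 CPM, and Tbl2 rose by 1.40 (SE 0.13) on the log2 scale. Atf3, a stress-induced transcription factor, rose by 0.41 (SE 0.12), but its adjusted p was 0.0675 without vehicle replicate 3. Gadd45a stood at 80.6 ± 30.7 CPM with vehicle and 100.1 ± 9.97 with 11j and did not pass (adjusted p = 0.141). Without vehicle replicate 1 its log2 change was 0.66 and passed (adjusted p = 1.31e-05). Over the list of 23 measured targets, 15 rose, 1 fell and 7 did not pass (median 0.54, camera adjusted p = 0.000634; adjusted p = 0.0722 with an estimated correlation).

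Host genes of small nucleolar RNAs (snoRNAs), whose spliced transcripts carry short reading frames and are classical NMD substrates, had the largest median change of any list tested. Of 18 measured, 15 rose, 2 fell and 1 did not pass, with a median log2 change of 2.46. Gas5 (chromosome 1, 161034422 to 161038539) rose 5.91-fold, from 523.4 ± 159 to 3092 ± 492 CPM. Snhg12 (chromosome 4, 132308623 to 132311024) rose from 49.7 ± 8.44 to 882.1 ± 80.8 CPM and Snhg15 (chromosome 11, 6525591 to 6528760) from 20.2 ± 0.425 to 391.6 ± 11.8 CPM. Snhg17 rose by 4.03 (SE 0.13) and Epb41l4aos by 3.26 (SE 0.09) on the log2 scale. Snhg14 and Snhg11 fell by 0.73 (SE 0.14) and by 1.00 (SE 0.32). Gas5, Snhg12 and Epb41l4aos overlap annotated snoRNAs at their 3′ end, and Snhg15 has a near-identical copy there, so their reads cannot be fully assigned. The set stood above other genes (camera adjusted p = 2.9e-07; adjusted p = 0.0722 with an estimated correlation).

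Splicing factors that carry poison exons, which bring a premature stop codon into part of their transcripts, were mostly higher. Of 30 measured, 20 rose, 4 fell and 6 did not pass. Tra2b rose from 193.1 ± 22.0 to 2011 ± 324 CPM (log2 change 3.37, SE 0.15), Luc7l, which overlaps an annotated pseudogene, by 2.08 (SE 0.10), Hnrnpdl by 1.67 (SE 0.10) and Rbm39 by 1.25 (SE 0.10). Srsf1, Srsf5, Rbm3 and Son were the 4 that fell, by 0.96, 0.60, 0.60 and 0.55. As a set they stood above other genes (camera adjusted p = 0.000204; adjusted p = 0.209 with an estimated correlation).

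**Figure D1:**
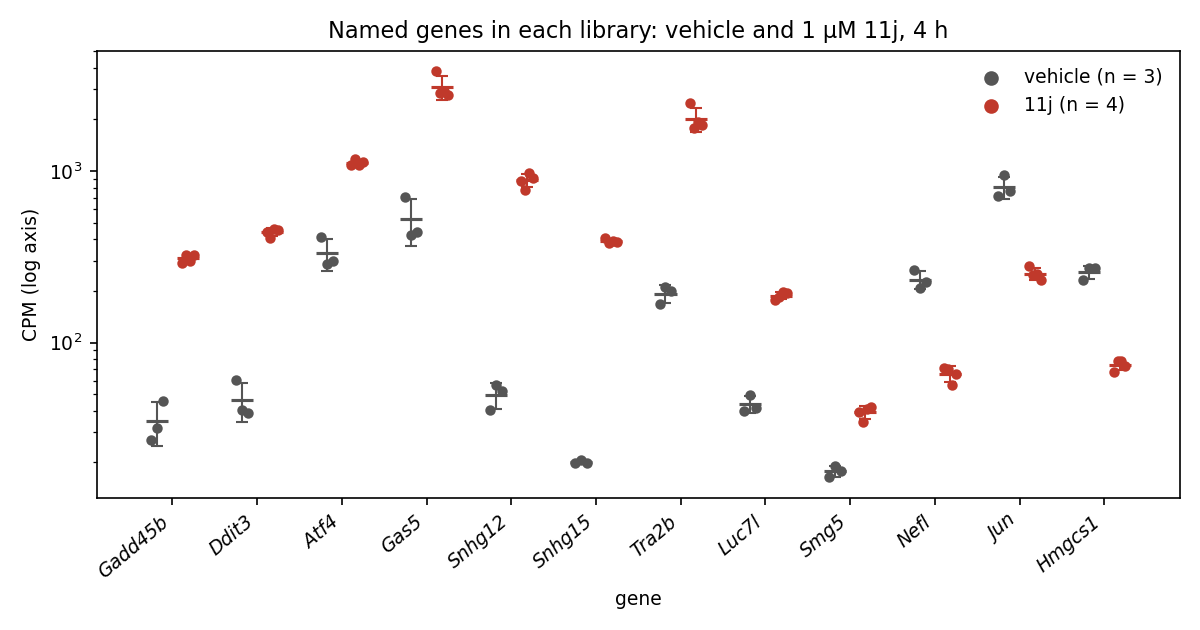
CPM on a log axis of 12 named genes in each library, with points for libraries, horizontal lines for group means and bars for the SD (3 vehicle in grey, 4 11j in red). The 11j libraries lie above every vehicle library for Gadd45b, Ddit3, Atf4, Gas5, Snhg12, Snhg15, Tra2b, Luc7l and Smg5, and below for Nefl, Jun and Hmgcs1.

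Genes of the integrated stress response stood above other genes as a set. Of 35 measured, 18 rose, 4 fell and 13 did not pass (median 0.43, camera adjusted p = 0.00579; adjusted p = 0.194 with an estimated correlation). Besides Ddit3 and Atf4, the members with the smallest p were Ppp1r15a, which encodes a regulatory subunit of the phosphatase that reverses eIF2α phosphorylation (62.6 ± 8.09 to 209.8 ± 9.98 CPM), and Trib3, a pseudokinase induced by ATF4 and CHOP (37.7 ± 2.41 to 94.5 ± 8.88 CPM). Asns, the asparagine synthetase that ATF4 induces, stood at 25.5 ± 4.56 and 29.3 ± 3.95 CPM and did not pass (adjusted p = 0.274). The cystine transporter gene Slc7a11, which overlaps an annotated pseudogene and also belongs to the list of NMD targets, fell by 0.86 (SE 0.15). The lists of NMD targets and stress response genes share 4 measured genes, so their tests are not independent. Among 14 aminoacyl-tRNA synthetase and tRNA export genes, 4 rose, among them Cars (0.74), and 5 fell, among them Tars, Iars and Lars (-0.84, -0.72 and -0.61), and the set did not pass (adjusted p = 0.598). Genes of the unfolded protein response of the endoplasmic reticulum went both ways, with 9 higher, 9 lower and 6 not past (camera adjusted p = 0.872). In that list the median (-0.009) and the mean (0.014) differ in sign. With single libraries left out, the median ranged from -0.082 (without vehicle replicate 2) to 0.006 (without 11j replicate 1). Syvn1, Manf and Vimp rose by 1.44, 0.88 and 0.97, whereas the lectin chaperone gene Canx fell by 0.91. Pseudogenes overlap Cars and Lars, and exons of other genes lie opposite the 3′ ends of Syvn1, Manf and Ppp1r15a, so their reads cannot be fully assigned. Hspa5, which encodes the chaperone BiP, stood at 3057 ± 373 and 2645 ± 166 CPM and did not pass (adjusted p = 0.248), but passed without vehicle replicate 1 (log2 change -0.30, adjusted p = 0.0458).

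Neuronal transcripts were lower in 11j cultures. Of 17 pan-neuronal markers, 15 fell, none rose and 2 did not pass, with a median log2 change of -0.85 (camera adjusted p = 2.04e-05; adjusted p = 0.0722 with an estimated correlation). The neurofilament genes Nefl and Nefm fell by 1.80 (SE 0.12) and by 1.59 (SE 0.13), Prph, a peripheral neuron intermediate filament, by 1.16 (SE 0.11), and Elavl3 by 1.62 (SE 0.17). Nefl was at 232.2 ± 28.0 CPM with vehicle and 65.9 ± 6.75 with 11j. Of 18 nociceptor genes, 13 fell, 2 rose and 3 did not pass (median -0.54, camera adjusted p = 0.0122; adjusted p = 0.187 with an estimated correlation). The voltage-gated sodium channel genes Scn9a and Scn10a fell by 1.27 (SE 0.15) and by 0.89 (SE 0.15), the neurotrophic receptor gene Ret by 1.05 (SE 0.11), the peptide gene Adcyap1 by 0.88 (SE 0.13) and Gfra2 by 0.97 (SE 0.16). Annotated pseudogenes overlap Nefm and Scn9a. Calca, which encodes the peptide CGRP, fell from 206.0 ± 27.0 to 142.6 ± 6.64 CPM. Trpv1, the capsaicin receptor gene, stood at 4.89 ± 1.17 and 4.78 ± 0.620 CPM and did not pass (adjusted p = 0.953). Of 8 mechanoreceptor and proprioceptor genes, 6 fell, none rose and 2 did not pass (median -0.72, camera adjusted p = 0.0254; adjusted p = 0.187 with an estimated correlation). That call was also lost with a minimum of 5 CPM (adjusted p = 0.0630). Ntrk2, Nefh, Spp1 and Etv1 fell by 1.44, 1.45, 1.47 and 0.79 on the log2 scale. Of 18 nerve injury genes, 10 fell, 2 rose and 6 did not pass (median -0.44, camera adjusted p = 0.0254; adjusted p = 0.187 with an estimated correlation), with falls in Flrt3, Sema6a, Nts and Jun of 1.78, 1.73, 1.36 and 1.67.

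Satellite glia markers stood below other genes as a set, and the Schwann cell list missed the threshold. Of 11 satellite glia markers, 7 fell, none rose and 4 did not pass (median -0.64, camera adjusted p = 0.0319; adjusted p = 0.187 with an estimated correlation). The potassium channel gene Kcnj10 fell by 1.69 (SE 0.16), the myelin protein gene Plp1 by 1.18 (SE 0.16), Cdh19 by 1.15 (SE 0.20) and Sparcl1 by 0.67 (SE 0.14). Of 13 Schwann cell markers, 8 fell, 1 rose and 4 did not pass, and the set (camera adjusted p = 0.0609; fry adjusted p = 0.000174, down) passed without vehicle replicate 1 (adjusted p = 0.0162) or 11j replicate 4 (adjusted p = 0.0354). It also passed with sample quality weights (adjusted p = 0.0405) and scaling to protein-coding genes (0.0461), but not with an estimated correlation (adjusted p = 0.194). Strain as a term (0.0284) and the replicate block (0.0286) let it pass too. These terms absorb vehicle replicate 1 and 11j replicate 4, so they are not separate from leaving those libraries out. Scn7a, S100b and Egr2 fell by 1.71, 0.97 and 1.06, and the periaxin gene Prx rose by 1.41. Among 12 fibroblast markers 6 fell, with Postn, Lum, Dcn and Fn1 lower by at least 0.96, 2 rose and 4 did not pass (camera adjusted p = 0.163; fry adjusted p = 0.0038, down). Macrophage markers went both ways, with 5 higher and 4 lower of 13 (adjusted p = 0.872), counts that depended on single libraries: 1 was higher and 2 lower without vehicle replicate 3, and 2 were higher and 2 lower without vehicle replicate 2 or 11j replicate 3. Without 11j replicate 1 or 11j replicate 2, 4 were higher and 2 lower, and without 11j replicate 4, 3 were higher and 4 lower. Their median (0.04) and mean (-0.04) differ in sign, as do the directions of the camera (up) and fry (down) tests. With single libraries left out, the median ranged from 0.02 (without 11j replicate 4) to 0.26 (without vehicle replicate 2). Mrc1 and Laptm5 fell by 1.71 and by 0.57, while Tyrobp and Cd68 rose by 0.41 and by 0.47. The last 2 lost their calls without vehicle replicate 3 (adjusted p = 0.0669 and 0.0795). Tyrobp also lost its call without vehicle replicate 2 (adjusted p = 0.0569), and Cd68 with the replicate block (adjusted p = 0.0598). Of 9 endothelial and pericyte markers, 2 rose and 3 fell (adjusted p = 0.83). Egfl7, with an exon of Agpat2 opposite its 3′ end, rose from 31.5 ± 8.28 to 89.4 ± 4.25 CPM and Pecam1 by 0.62, the latter not without vehicle replicate 3 (adjusted p = 0.0652), while Cdh5 and Flt1 fell by 0.84 and by 0.74. Erythroid markers were measured in too few genes for a test.

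Immediate-early genes, a list of transcription factors together with phosphatases and other early-induced genes, split into falling and rising members. Of 23, 11 fell, 7 rose and 5 did not pass, with a median of -0.58. The set did not stand apart from other genes (camera adjusted p = 0.331), while fry, which tests whether its genes move on balance in the same direction, called it lower (adjusted p = 0.00812). Egr1 fell from 802.1 ± 349 to 86.3 ± 8.10 CPM, Jun from 806.6 ± 119 to 252.0 ± 19.3, and Fosl2 and Junb, the latter with an exon of Prdx2 opposite its 3′ end, by 1.28 and by 0.85 on the log2 scale. Fos fell from 119.4 ± 68.8 to 46.6 ± 7.91 CPM with overlapping groups (adjusted p = 0.0143), a log2 change of -1.16 that became -0.39 and did not pass with sample quality weights (adjusted p = 0.0726). Without vehicle replicate 1 it was -0.74 and passed (adjusted p = 0.00301). Cytokine and NF-κB genes had 3 members higher and 5 lower of 16 (adjusted p = 0.83), but 7 higher and 5 lower without vehicle replicate 1. Ccl5 rose by 1.62, and Cxcl1, Ccl7 and Nfkbia fell by 1.56, 1.03 and 0.82. Il6 was at 31.0 ± 31.5 CPM with vehicle and 27.9 ± 3.94 with 11j and did not pass (adjusted p = 0.622). Without vehicle replicate 1, the C57BL/6J culture, its log2 change was 1.05 (adjusted p = 2.99e-07).

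**Figure D2:**
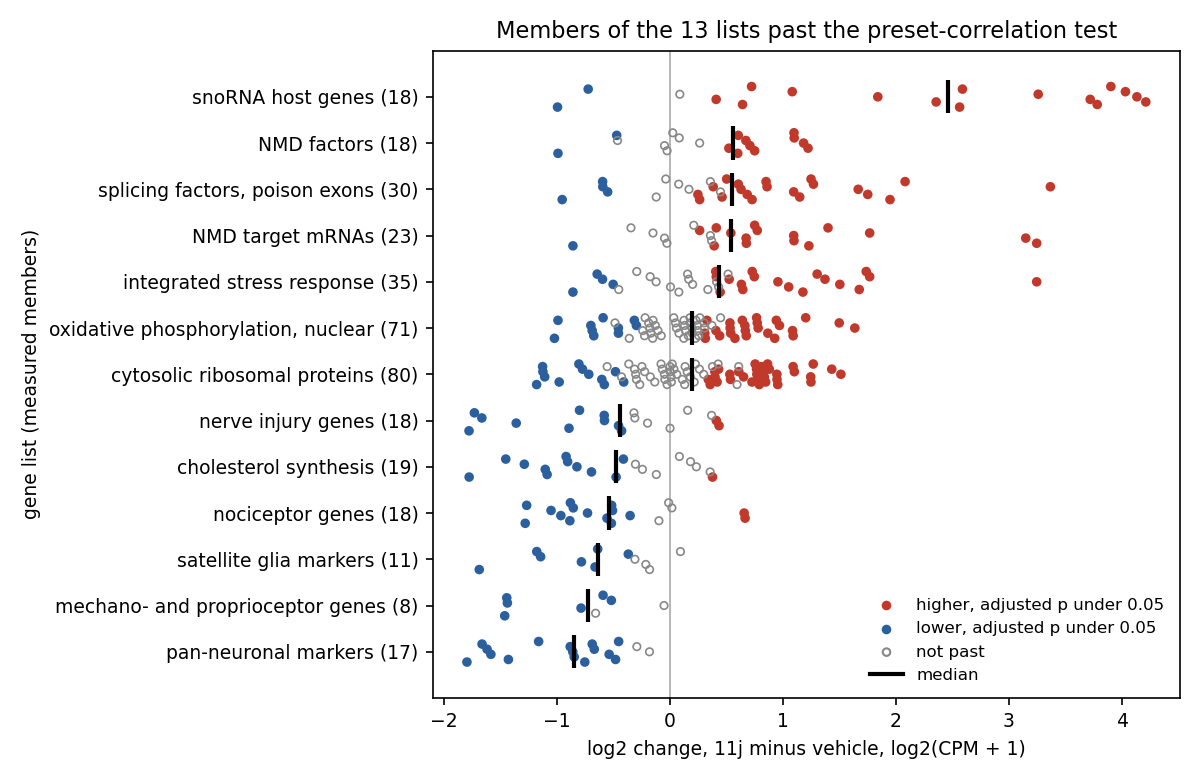
Log2 change (11j minus vehicle, log2(CPM + 1)) of each measured member of the 13 lists that passed the test with a preset correlation, with members past an adjusted p of 0.05 filled (red higher, blue lower), others open, and the median as a black bar. Medians range from 2.46 for snoRNA host genes to -0.85 for pan-neuronal markers, and every list except the pan-neuronal, mechano- and proprioceptor and satellite glia lists has members called in both directions.

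Among metabolic and housekeeping groups, cholesterol synthesis genes were lower. Of 19 measured, 11 fell, 1 rose and 7 did not pass (median -0.48, camera adjusted p = 0.0281; adjusted p = 0.209 with an estimated correlation). Hmgcs1 fell from 257.7 ± 22.4 to 74.3 ± 5.02 CPM, the receptor gene Ldlr by 1.29, Cyp51, which lies opposite exons of Akap9, by 1.09 and Hmgcr, the rate-limiting enzyme of the pathway, by 0.83 on the log2 scale. Heat shock genes had 7 members lower and 3 higher of 14 (camera adjusted p = 0.105; fry adjusted p = 0.000724, down), and Hsp90aa1, Hspd1 and Hspa1b fell by 1.92, 1.15 and 0.90. Hspa8, whose 3′ end has near-identical copies, fell by 0.86. Cytosolic ribosomal protein genes (80 measured, 32 higher, 12 lower, 36 not past, median 0.20, camera adjusted p = 0.0404) and nuclear genes of oxidative phosphorylation (71 measured, 25 higher, 10 lower, 36 not past, median 0.20, camera adjusted p = 0.0480) were slightly higher as sets. With an estimated correlation their adjusted p = 0.893 and 0.715, and both calls were lost without vehicle replicate 2 (adjusted p = 0.291 and 0.0951), vehicle replicate 3 (0.182 and 0.109) or 11j replicate 1 (0.0886 and 0.0957). The ribosomal list also did not pass with fry (adjusted p = 0.219), quantile normalization (0.0645) or a minimum of 5 CPM (0.0650). The oxidative phosphorylation list, which passed with fry (adjusted p = 0.0296), was also lost without 11j replicate 3 (0.0671), with a minimum of 5 CPM (0.0954) and with limma without a trend (0.0536). Without vehicle replicate 1, the C57BL/6J culture, the medians were 0.39 for ribosomal protein genes (47 higher, 11 lower, adjusted p = 0.000173) and 0.31 for oxidative phosphorylation genes (39 higher, 12 lower, adjusted p = 0.0162). The ribosomal median was 0.07 without vehicle replicate 2 and 0.12 without vehicle replicate 3, and the oxidative phosphorylation median was 0.13 without vehicle replicate 3. The mean log2 level of the ribosomal list was 9.65 in vehicle replicate 1, 9.06 and 9.07 in vehicle replicates 2 and 3, and 9.38 to 9.58 in the 11j libraries. Rps29 and Rpl28 rose by 1.27 and by 1.24, and Ndufa12 and Ndufa7 by 1.08 and by 0.97, whereas Atp5a1 fell by 0.99. Rps28 and Rps11 rose by 1.51 and by 0.83, and Ndufv3 from 43.1 ± 2.95 to 124.0 ± 15.4 CPM, but these 3 have near-identical copies at their 3′ ends, and Rpl28 lies opposite an exon of Ube2s. Targets of p53 had 4 members higher and 4 lower of 18 (adjusted p = 0.83; 3 higher and 2 lower without 11j replicate 3), with Sesn2 and Bbc3 higher by 0.75 and by 0.53 and Gdf15 and Zmat3 lower by 0.65 each. Nrf2 targets had 2 higher and 3 lower of 15 (adjusted p = 0.83; 4 higher and 5 lower without vehicle replicate 1), with Osgin1 higher by 1.12, Ftl1, which has near-identical copies, higher by 1.56, and Hmox1 lower by 1.25. Of 15 proliferation genes 7 fell and 3 rose (adjusted p = 0.377), with falls of 1.93 in Mcm4, 0.85 in Mcm6 and 0.63 in Mki67 and a rise of 0.72 in Tyms. Of 4 sex-linked genes, the Y-linked Kdm5d, whose 3′ end has a near-identical copy, rose by 0.89, Ddx3y, which overlaps a pseudogene, fell by 0.45, and Eif2s3y and Uty did not pass. That list did not pass (adjusted p = 0.884), and its median (-0.09) and mean (0.07) differ in sign. The call of Ddx3y was lost without 11j replicate 1 (adjusted p = 0.0569) or 11j replicate 3 (adjusted p = 0.0612), and with scaling to protein-coding genes (adjusted p = 0.0515).

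The largest rises with 11j included the mitochondrial ribosomal RNAs. Mt-Rnr1, the 12S rRNA (mitochondrial genome, 70 to 1024), rose from 99.4 ± 44.4 to 12138 ± 2413 CPM (log2 change 6.98, SE 0.26), and mt-Rnr2, the 16S rRNA (1094 to 2675), from 791.4 ± 631 to 19289 ± 4115 CPM (log2 change 4.86, SE 0.40). Together they made up 0.167%, 0.0471% and 0.0532% of the values in the vehicle libraries and 2.90%, 3.85%, 2.42% and 3.41% in the 11j libraries. The mRNAs of the mitochondrial genome went both ways, with 5 higher, 3 lower and 4 not past of 12 (median 0.29, adjusted p = 0.598). The median was 0.73 without vehicle replicate 1 (7 higher, 3 lower), 0.14 without vehicle replicate 2 and 0.03 without vehicle replicate 3 (4 higher and 3 lower in both), and the mean log2 level of the list was 7.88 in vehicle replicate 1, against 6.83 and 6.89 in the other vehicle libraries. Mt-Atp8 and mt-Nd5 rose by 2.46 and by 2.14, while the log2 changes of mt-Nd6 and mt-Co2, which fell, were -1.68 and -2.39. Overlapping genes or a near-identical copy make the assignment of these 4 mRNAs uncertain. Of 43 genes for rRNA and short non-coding RNA, 33 rose and 5 fell (median 1.27), and the 13 snoRNA and scaRNA genes had a median of 1.25. Other large rises were in Shcbp1 (16.5 ± 1.66 to 704.1 ± 92.6 CPM), Lzts1 (8.27 ± 3.06 to 314.6 ± 51.4), Agbl2 (1.23 ± 0.564 to 43.1 ± 2.70) and Slc25a43, a mitochondrial carrier gene (0.485 ± 0.0678 to 82.1 ± 6.18). Annotated pseudogenes overlap Shcbp1 and Agbl2, and Slc25a43 has a near-identical copy at its 3′ end, so these 3 are uncertain.

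**Figure D3:**
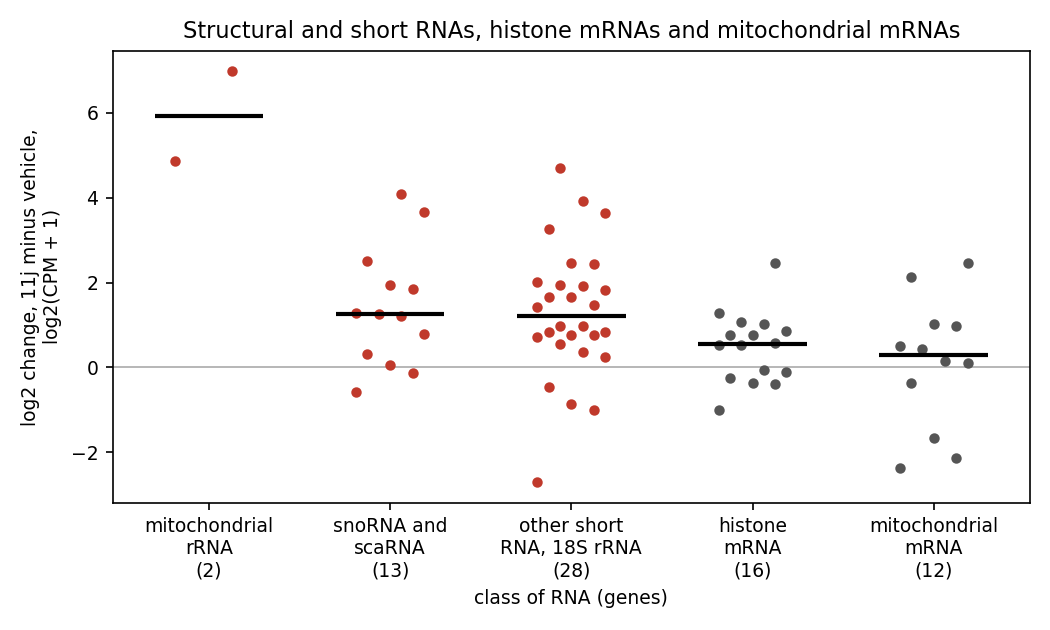
Log2 change (11j minus vehicle, log2(CPM + 1)) of genes in 5 classes of RNA, with a point per gene and the median as a black bar. The 12S and 16S rRNAs lie at 6.98 and 4.86, above all 12 mitochondrial mRNAs, of which mt-Atp8 is highest at 2.46.

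The largest falls were in Vps8, a gene for endosomal tethering, from 8962 ± 1057 to 241.2 ± 20 CPM (chromosome 16, 21423118 to 21644680; log2 change -5.21, SE 0.13), and in D3Ertd254e, from 393.8 ± 87.7 to 10.7 ± 1.59 CPM. Ccdc36 fell from 592.1 ± 154 to 19.2 ± 4.63 CPM, the kinesin gene Kif3a from 946.2 ± 66.7 to 45.3 ± 8.22 and the cytochrome P450 gene Cyp2e1 from 90.8 ± 1.52 to 6.63 ± 0.761. Near-identical copies at the 3′ ends of these 3 genes make their levels uncertain. Falls in Cyp4x1 (log2 change -3.65, SE 0.21), in Timm22, a subunit of the mitochondrial inner membrane translocase (-3.46, SE 0.23), and in Adm, which encodes adrenomedullin (-3.38, SE 0.16), completed the 8 largest. Passed over in naming the 8 largest changes in each direction were 5 predicted genes or pseudogenes that rose and 4 that fell.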

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

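No test in this part was chosen after the result was seen. Among the 4 11j libraries, a value was picked out when its gap to the nearest of the others as a share of the whole range exceeded Dixon's critical value at the 95% level. Of 162 genes, list means and library measures examined, 8 met this, and chance gives about 1 in 20. Vehicle libraries, with 3 per group, were not examined. In 11j replicate 1, Gas5 was at 3822 CPM (others 2762 to 2938), Cxcl1 at 11.4 (7.11 to 7.83) and S100b at 223.3 (206.4 to 209.2), each the highest. In the same library Kif3a was at 33.0 CPM (others 48.8 to 50.2), Zmat3 at 61.1 (70.4 to 71.2) and Snhg17 at 56.1 (60.2 to 61.0), each the lowest. In 11j replicate 4, Fn1 was at 1371 CPM (others 1136 to 1171), and the mean log2 level of the p53 target list was 6.10 (others 6.13 in all 3). Each of the 7 genes also passed the test without the library named.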

How the results depend on the processing

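The rescaling to protein-coding genes and the unequal-variance test on untransformed CPM were chosen after seeing the data; the other alternatives were fixed before. Leaving out each library in turn gave 6662 to 8774 changed genes, 3141 to 4238 higher and 3521 to 4536 lower, and 11 to 14 lists past the threshold. The alternatives that moved these counts by more than 1.5 times were a log2 change of at least 1 (2213 genes, 1160 higher and 1053 lower), which is stricter by construction, and the unequal-variance test (4081 genes, of which 1596 were lower), for which the cause was not tested. No list passed with an estimated correlation (0 of 27), and the cause was not tested. Some of the lists that lost their call had an estimate below the preset 0.01. For the NMD targets the estimate was 0.000384, yet the unadjusted camera p went from 9.39e-05 to 0.00774. In such lists a correlation above the preset value is not what cost the call. Other settings gave between 6504 (a minimum of 5 CPM) and 9972 genes (sample quality weights). Strain as a term, which rests on vehicle replicate 1 alone, gave 8848. The minimum of 5 CPM left 9 lists past, without those of NMD factors, mechanoreceptor and proprioceptor genes, ribosomal proteins and oxidative phosphorylation. Counts of 1 or 2 list members in a direction (snoRNA host, nerve injury, nociceptor, fibroblast, endothelial, cholesterol and sex-linked lists) dropped by 1 without some single libraries. No named gene or list that had passed the test changed direction under these alternatives. Scaling moved the median of all genes from -0.05 to at most 0.02 and the share of calls that were higher from 47.1% to 50.4% or 53.4%. With the replicate number as a block, 6784 genes and 14 lists passed, 6654 of the genes shared with the main test. The numbers did not pair the cultures: deviations of same-numbered cultures correlated at 0.175, -0.198 and 0.0987, and not every culture correlated best with its own number. In simulated data at these depths, with a dispersion of 0.01 and no outlying library, 1.5-fold changes were recovered in 83.6% of genes. Some real genes spread more widely, so this need not be the recovery in the real libraries. DESeq2 was not run because the table does not hold counts.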

Other observations

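Tests of a library batch, of mitochondrial RNA as a whole and of immediate-early genes among the falls were chosen only after the result was seen; the size that counts as a large fall and the settings for copies were also set then, and the comparison of copies was repeated once to use genes of like level, as first planned, and the comparison by SD and the hosts of at least 3 snoRNAs were added to the snoRNA test.

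Long non-coding transcripts leaned upward and processed pseudogenes downward. Of 233 lincRNA genes tested 103 were higher and 38 lower with 11j (median log2 change 0.34), and of 153 genes of the processed transcript class 78 were higher and 17 lower (median 0.47). Of 164 processed pseudogenes, 37 were higher and 71 lower (median -0.29). Protein-coding genes had 3139 higher and 3815 lower of 12293 (median -0.07). CPM values share a common total, and protein-coding genes summed to 933837 CPM with vehicle and 885060 with 11j. After scaling to protein-coding genes, 4045 of all tested genes were higher and 3535 lower. A lean as small as that of protein-coding genes therefore depends on the scaling.

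Protein-coding genes with an annotated NMD transcript had a higher mean log2 change than genes without, and a hypothesis is that 11j stabilises such transcripts. Against genes of like level and transcript number, the 3524 genes with an NMD transcript had a mean log2 change higher by 0.25 (permutation p = 0.0005 over 2000 draws, the smallest they can give). Of these, 1226 (34.8%) were higher with 11j, 839 were lower and the others did not pass; the median was 0.11. Of the 8769 genes without, 21.8% were higher and the median was -0.14. As a control, genes with a retained-intron transcript but no NMD transcript differed from like genes by 0.01 (permutation p = 0.466). Genes are not independent replicates, and the treatment coincides with the library series, so this pattern may have a technical part.

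Longer genes were lower with 11j. Across 12293 protein-coding genes, the Spearman correlation of the log2 change with genomic length was -0.191, a correlation across genes and not across samples. With genes in 5 groups of equal size by length, the shortest (median 4.79 kb) had a median change of 0.10 and the longest (133.4 kb) of -0.29. A hypothesis is that transcription of long genes was reduced over the treatment, which was not tested further. Because the treatment coincides with the library series, the pattern may also have a technical part.

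Of the 35 splits of the 7 libraries, 1, the real split, gave as many changed genes (7623), and the highest other split gave 0. Every other split mixes groups that the first principal component already separates, so this largely restates that separation. With only 35 splits, chance in the grouping cannot be fully excluded. A library batch that coincides with the treatment cannot be told apart from 11j, since 0 series of library codes hold both groups.

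The rise of mitochondrial rRNAs and short non-coding RNAs stood out among RNA classes, with medians of 5.92 for the mitochondrial rRNAs and 1.27 for all 43 genes. The tables argue against more mitochondrial RNA as a whole: the highest mitochondrial mRNA rose by 2.46 (SE 0.23), against 4.86 (SE 0.40) for the lower of both rRNAs. The median mRNA lay 2.96 SD below that rRNA, just short of the bound of 3 SD set first, and the comparison by SE was added afterwards. Whether a higher share of RNA without a poly(A) tail in the 11j libraries contributes stays open. The 16 histone genes, chosen by symbol alone, had a median change of 0.55 (quartiles -0.14 and 0.90), barely above the bound of 0.5. Of these, 9 rose and 2 fell. Whether each of their mRNAs lacks a poly(A) tail was not checked. An effect of 11j on histone mRNAs themselves could give the same rise, so the test cannot decide. The histone median is smaller than either rRNA change. The 18S rRNA gene Rn18s-rs5 also rose, from 4089 ± 1011 to 7178 ± 2894 CPM (limma adjusted p = 0.0486). A library batch, the step of rRNA depletion included, and an effect of 11j cannot be told apart here, because they coincide.

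Falls of at least 4-fold among genes with a mean of at least 5 CPM (76 genes) may in part reflect how reads were assigned among copies. Of these, 36.8% had a near-identical copy or an overlapping pseudogene, against 15.96% of 1435 other genes of like level (Fisher's exact test, two-sided, p = 2.42e-05). Some of the 76, such as Cd63-ps and Gm15464, are annotated pseudogenes, which by their nature resemble another gene. The comparison matched level but not gene type, so part of the difference may only restate that pseudogenes fell. Copies were also more frequent among rises of at least 4-fold (22.8% of 158 genes; Fisher's exact test, two-sided, against all other genes with a mean of at least 5 CPM, p = 0.00393), and whether falls and rises differ in this was not tested. Genes on the list of immediate-early genes make up 1.32% of the 76, so they are not the bulk of the falls. That list holds only 23 measured genes, whose changes had already been seen. A loss of other short-lived mRNAs was not tested. Of the falls, 48, Vps8 among them, have no near-identical copy or overlapping pseudogene. For these the treatment and a batch stay open, and other ways in which reads could be misassigned or counted differently were not tested.

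For the rise of snoRNA host genes, the tables argue against a general rise of long non-coding RNAs: the list's median of 2.46 lay above all of 10000 lists of other long non-coding RNAs of like level (percentile 100, highest 2.12). Holding a snoRNA did not by itself go with a rise: 232 protein-coding genes that hold a snoRNA on the same strand, with a median vehicle level (45.6 CPM) close to that of the list (43.1 CPM), had a median change of -0.00161 (log2, quartiles -0.33 and 0.46, 70 higher and 54 lower), 2.92 SD below that of the list. Among the 27 of them with at least 3 snoRNAs the median was 0.23 and the highest 3.09. The 232 genes were not matched to the list for the number or position of their snoRNAs. The test therefore cannot decide how far reads of intronic snoRNAs contribute to the rise of the list. That NMD inhibition raises these transcripts remains a hypothesis, as the library batch and such reads stay open.

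In the deposited table, 21 genes, among them septins (Sept), membrane-associated RING finger genes (March) and Selenof, carry a date number in place of their symbol. Their deposited p-values, from the authors' deposited table, lie between 0.385 and 0.392 whatever their levels. All 21 are recovered within 1% when the date number is added to the vehicle values in the test. Recomputed without it, 4 pass an adjusted p of 0.05, namely Marc2, Sept10, Sept1 and Sept5. These 4 were chosen after their values were seen: Marc2 was at 125.9 ± 3.11 CPM with vehicle and 56.5 ± 1.93 with 11j, and Sept5 at 6.72 ± 0.902 and 15.9 ± 2.50.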
